A study of Mus musculus with 8 samples.

How the data were processed

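RNA from 8 sorted samples of spleen XCR1+ dendritic cells was measured on 1 array each. Per the labels' protocols, RNA was extracted with a column kit, and 3 or 20 ng was amplified in 2 rounds and labelled with biotin; which input each sample had is not given in the sources used here. If the input followed the groups, every difference between groups could carry an effect of it. The deposited values are log2 expression values per probe set made with RMA in the oligo package, per the submitters' processing notes. The versions and options of these steps and a genome build are not given in the sources used here. RMA's usual steps correct background, quantile normalize probes and summarise them per probe set, and the medians of the deposited columns still differed, from 5.25 to 5.46. Quantile normalization assumes that most genes differ little between samples, so a change of total RNA per cell is not visible in these values. No column of the table was left unused.

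The table held 35556 rows. Symbols came from the platform's annotation, in which 21789 rows had exactly 1 gene symbol, 1621 had several and 12146 were without a symbol in the table used. Of the gene identifiers, 21698 were found in a mouse gene table of the assembly GRCm38.p6, from which no coordinates are printed. Rows with several symbols or none entered no named result. For the 999 genes with more than 1 row the row with the highest mean was used, which left 19938 genes. Rows of 1 gene were called in opposite directions for 2, 3 and 0 genes in the 3 pairwise comparisons. A background mark of 4.98 was taken from the 95th percentile of 1194 olfactory and vomeronasal receptor genes, and 12934 genes had a group mean above it. No gene was removed for low values before testing. Where the mean of a group lay below the mark, a called change is given as a bound, with per array the higher of the mark and the value standing for that group. This held for 487, 1003 and 136 called genes in the 3 pairwise comparisons, of which 189, 387 and 20 allow no bound.

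Groups came from the sort described in the labels: immature (n = 3), CCR7+Il12b- (n = 3) and CCR7+Il12b+ (n = 2). All 8 samples entered 1 linear model with 3 group means in limma 3.58.1 (R 4.3.3), fitted with lmFit and eBayes, with 5 residual and 5.86 prior degrees of freedom. Tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method over all 19938 genes, and a gene was called at an adjusted p under 0.05. Each change is a difference of log2 means with the standard error of the model. The labels do not say that replicates came from separate mice, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. The comparisons, the test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

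In each pairwise comparison the rule named the 10 largest measured rises and the 10 largest measured falls among called genes without overlap between samples, at most 4 members of each list with the largest change, and Ccr7, Il12b, Itgax, Cd8a, Bst2 and Xcr1. Predicted genes and multigene families were passed over, a gene named in 1 comparison could be given in the others, and genes beyond this rule are said to be chosen after their values were seen.

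The 26 gene lists hold 510 entries, 469 of them measured as 1 symbol, 3 through an older name. The others were not analysed here. Genes of the sort stayed in the lists, with Ccr7 and Xcr1 in migration, Il12b in cytokines and Xcr1, Cd8a and Itgax in identity. Bst2 stayed among interferon-stimulated genes and plasmacytoid markers. Counts and tests of these lists include them, and no list was tested without them. The lists are co-stimulatory and co-inhibitory genes, migration and cytoskeleton, NF-kB, cytokines and their receptors, chemokines, interferon-stimulated genes, pattern recognition and uptake receptors, class I and class II presentation, XCR1+ dendritic cell identity, cell cycle, cholesterol synthesis and uptake, liver X receptor targets, tolerance-associated and feedback genes, apoptosis regulators, glycolysis, mitochondrial respiration, immediate-early and heat-shock genes, and markers of B, T and NK cells, plasmacytoid and CD11b+ dendritic cells, monocytes and macrophages, neutrophils and erythroid cells. Each list was set against all other genes with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 26 lists of a comparison. The same test with a correlation estimated from the data called 0 of 26 lists in each comparison, where the preset called 12, 12, 13 and 8. The fry test, which asks whether a list's genes move one way on balance and does not compare them with other genes, called 18, 20, 11 and 22. Olfactory and vomeronasal receptor genes had median log2 changes against immature cells of 0.0979 in CCR7+Il12b- and 0.0995 in CCR7+Il12b+ cells. A shift of that kind can enter the fry calls.

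Both comparisons against immature cells share their controls, so unchanged groups sharing the same 3 samples were simulated 100 times from the fitted spreads. The gene test was tested on simulated data with independent normal noise of the fitted spreads and 200 changed genes among 19938. A further small set of genes, shifted for the list test, was left out of the false calls. More genes were called in the real data, so recovery there may differ. It recovered 100%, 99%, 97% and 100% of 2-fold changes in the 4 comparisons in the order given, and 100% of 4-fold changes in each, with 8, 13, 15 and 15 false calls.

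Alternatives tried were median centring, cyclic loess or another quantile normalization of the arrays, a filter on dim genes (above the median of all values in at least 2 samples, or a mean above the 30th percentile), the mean of a gene's rows or every row of the table, a robust variance with trend, array weights, fits on the compared groups alone, a 2-group model of matured against immature cells, the replicate number as a fixed or random block, a stricter threshold, a test against a 2-fold change, and leaving out each sample in turn.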

Results

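Gene expression was measured on 8 arrays of XCR1+ dendritic cells from the spleen of untreated mice carrying a yellow fluorescent reporter in the Il12b gene. XCR1+ dendritic cells are the conventional dendritic cells that also carry CD8α in the spleen and are known for cross-presenting antigen to CD8 T cells. Cells lacking lineage markers, with no or little BST2, high CD11c and CD8α, had been sorted into an immature fraction without CCR7 and without reporter (n = 3), a fraction with CCR7 but without reporter, called CCR7+Il12b- here (n = 3), and a fraction with both, called CCR7+Il12b+ here (n = 2). CCR7 is the chemokine receptor that dendritic cells gain as they mature. The series title states the purpose, which was to follow maturation that takes place in part of these cells without infection or other treatment. Array medians lay between 5.25 and 5.46 on the log2 scale, and the number of arrays limits the precision of every value.

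The genes behind the sort were looked at first, as a check of the labels. The fractions were separated on CCR7 and the reporter, so Ccr7 and Il12b are no findings. All genes behind the sort are also members of gene lists below, where the sort on CCR7 and the reporter favours rises of Ccr7 and Il12b. Ccr7 was at 8.50, 8.86 and 8.56 (log2) in the immature samples, higher by 3.59 ± 0.13 (SE) in the CCR7+Il12b- samples and by 3.97 ± 0.14 in the CCR7+Il12b+ samples. Il12b, which encodes the p40 subunit of interleukin 12, rose 13.7-fold in the CCR7+Il12b- fraction (log2 change 3.78 ± 0.11), although those cells had been sorted as negative for the reporter. It rose 38.2-fold in the CCR7+Il12b+ fraction (5.26 ± 0.12), and the direct difference between the matured fractions was 2.78-fold (1.48 ± 0.12, adjusted p = 0.000124). Xcr1 fell along the same order of groups, with changes of -1.36 ± 0.22 and -3.02 ± 0.25 against immature cells and -1.66 ± 0.25 between the matured fractions. Itgax, the gene of CD11c, changed by -0.97 ± 0.13 in CCR7+Il12b+ against immature cells, its value in CCR7+Il12b- cells was -0.06 ± 0.12 (adjusted p = 0.775), and the matured fractions differed by -0.91 ± 0.13. Bst2 differed from immature cells by -0.46 ± 0.14 (adjusted p = 0.0322) in the CCR7+Il12b- fraction, a call that ended when immature replicate 2 or 3 or CCR7+Il12b- replicate 1 or 3 was left out (adjusted p from 0.0954 to 0.138) and after loess (0.0955). In the CCR7+Il12b+ fraction Bst2 differed by -0.46 ± 0.15 (adjusted p = 0.0398), which did not pass without immature replicate 2 or 3 or either CCR7+Il12b+ replicate (0.103 to 0.145), after loess (0.158) or with a replicate block (0.0616). Cd8a differed by -0.31 ± 0.11 (adjusted p = 0.0473) in CCR7+Il12b+ against immature cells, and leaving out any sample other than CCR7+Il12b- replicate 3 ended that call (adjusted p from 0.0504 to 0.202). Between the matured fractions Cd8a differed by -0.44 ± 0.11 (adjusted p = 0.0312), a call that ended without any 1 sample other than immature replicate 1 or CCR7+Il12b- replicate 3 (0.0582 to 0.128). Both Cd8a calls also ended with array weights, a fixed replicate block or a fit on the compared groups alone (0.0561 to 0.0995). That against immature cells ended after loess, with either filter or with a random block (0.0531 to 0.0714), and that between the matured fractions after median centring (0.0505).

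**Figure D1:**
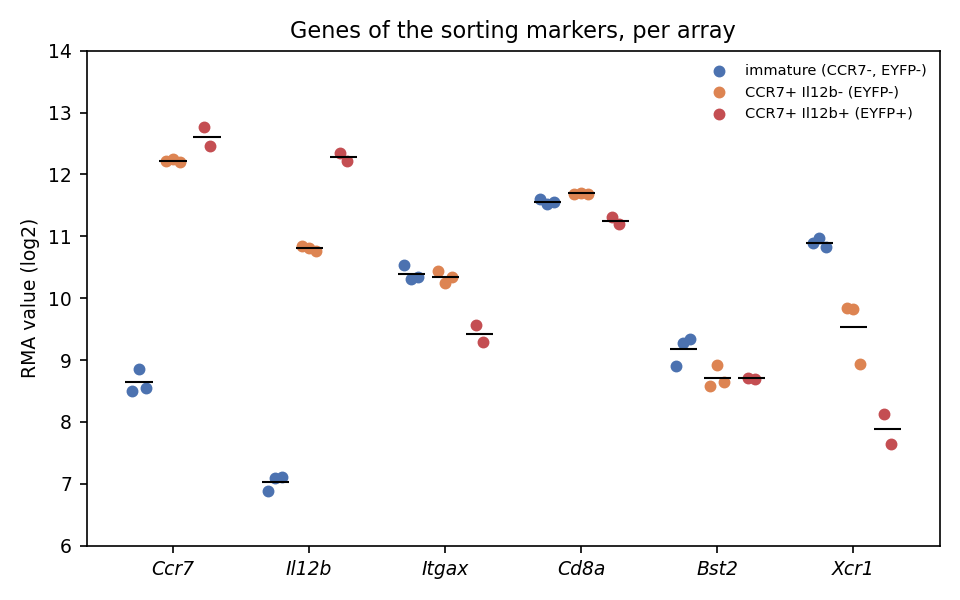
Log2 array values of the 6 genes behind the sort in each sample, by fraction, with points for samples and bars for group means. Ccr7 and Il12b are higher in all CCR7+ samples than in all immature samples, and Il12b differs by 1.48 on the log2 scale between the CCR7+ fractions.

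The 8 samples separated by fraction. Pearson correlations across genes were 0.992 to 0.996 among immature samples, 0.986 to 0.992 among CCR7+Il12b- samples and 0.987 between both CCR7+Il12b+ samples. Between fractions they were 0.942 to 0.968 for immature and CCR7+Il12b- samples, 0.911 to 0.92 for immature and CCR7+Il12b+ samples, and 0.973 to 0.981 for both matured fractions. The first principal component held 77.1% of the variance and put the immature samples at -47.8 to -55.8, the CCR7+Il12b- samples at 8.20, 13.4 and 30.1, and the CCR7+Il12b+ samples at 52.2 and 53.6. CCR7+Il12b- replicate 3 stood apart from the other two of its fraction, toward the CCR7+Il12b+ samples, and also had the lowest Xcr1 value of its fraction.

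**Figure D2:**
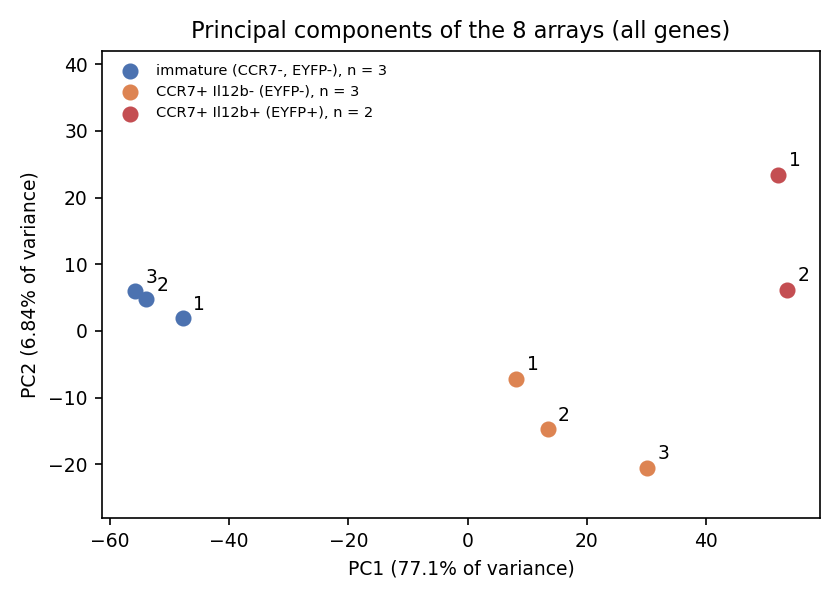
First and second principal components of the 8 samples over the genes tested, with the share of variance on each axis (77.1% and 6.84%) and 1 point per sample coloured by fraction. Along the first component the CCR7+Il12b- samples (8.20 to 30.1) lie between the immature samples and the CCR7+Il12b+ samples (52.2 and 53.6).

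The first comparison asked what differs in CCR7+Il12b- cells from immature cells. Cd63, a tetraspanin of endosomes, rose at least 67.5-fold (n = 3 in each group, adjusted p = 5.06e-09), a lower bound because its immature mean of 4.58 (log2) lay below the background mark of 4.98. Changes of other genes with a group below that mark are also given as bounds. Anxa3, an annexin, rose at least 46.6-fold, Socs2, a suppressor of cytokine signalling, at least 30.6-fold, and H2-M2, a non-classical class I molecule, at least 32.0-fold. The size for Socs2 depends on the table's row, since its rows gave log2 changes of 3.40 and 5.50 as measured. Fscn1, whose product fascin bundles actin in dendritic cell processes, rose 23.3-fold (log2 change 4.54 ± 0.18 SE), Adcy6 by 4.28, and Papss2, Slco5a1 and Nudt17 by at least 4.22, 4.10 and 4.59. Large falls were those of Serpinb10 (at least 6.93-fold), Serpinb2 (-2.78 ± 0.23), Anxa1 (-2.54 ± 0.20) and Tlr3, the receptor for double-stranded RNA (-2.23 ± 0.31). Other large falls were those of Nifk, Sdad1, Unc119 and Arhgap18, between -2.05 and -2.14.

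In total 4706 of 19938 genes changed at an adjusted p under 0.05 in limma's moderated test, with 1814 higher and 2892 lower in CCR7+Il12b- cells. Of these, 1217 changed at least 2-fold as measured, 576 up and 641 down. Over all genes, the samples of both groups did not overlap for 8243 of 19938, where chance gives 10%.

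Genes of NF-kB signalling rose as a group. All 19 measured members rose, with Relb, an NF-kB subunit, up 7.88-fold (2.98 ± 0.12), Birc2 by 2.74 ± 0.11 and Traf1 by 2.27 ± 0.11. The size for Birc2 depends on the table's row, since its rows gave 1.56 to 2.74. All 19 also rose when adjusted over the list alone, and the list moved against all other genes at an adjusted p of 3.55e-19 (adjusted p = 0.165 with an estimated correlation). Of 18 co-stimulatory and co-inhibitory genes, 12 rose and 2 fell, or 13 and 3 adjusted over the list alone. Tnfrsf4, the gene of OX40, rose by 3.13 ± 0.18, Cd274, the gene of PD-L1, by 2.42 ± 0.14 and Cd40 by 2.06 ± 0.10, while Havcr2 was among the falls (-1.54). The list was called up at an adjusted p of 8.67e-07 (adjusted p = 0.165 with an estimated correlation). Tolerance-associated and feedback genes gave 10 rises and 4 falls among 19, the same counts adjusted over the list alone, with Socs2, Cd274, Cd200 (2.18 ± 0.15) and Pdcd1lg2 (at least 2.82-fold) rising most and Ctla4, Tnfaip8l2 and Ahr among the falls. Their adjusted p was 0.00028 (adjusted p = 0.212 with an estimated correlation).

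More chemokine and cytokine genes rose than fell. Among 16 chemokines 8 rose and 1, Ccl4, fell (-0.83), and counts adjusted over the list alone were the same. Ccl5 rose 15.5-fold, Ccl22 12.6-fold and Ccl19, a ligand of CCR7, 6.05-fold. The test gave an adjusted p of 0.000429 (adjusted p = 0.165 with an estimated correlation). Of 22 cytokine and cytokine receptor genes 11 rose and 4 fell (11 and 4 adjusted over the list alone), led by the receptor genes Il21r (3.85 ± 0.14), Il7r (3.20 ± 0.15) and Il15ra (3.10 ± 0.14), with falls of Il1a, Il18, Ifngr1 and Tgfb1, of which Il1a, Il18 and Tgfb1 were chosen after their values were seen. Its adjusted p was 0.000745 (adjusted p = 0.261 with an estimated correlation). Migration and cytoskeleton genes gave 10 rises and 5 falls among 17 (10 and 6 adjusted over the list alone). Anxa3, Fscn1 and Ccr7, on which the cells were sorted, rose most. The chemokine receptors Ccr2 (-1.94 ± 0.26), Ccr9 (-1.64 ± 0.19) and Xcr1 were among the falls, together with Itgae. The adjusted p was 0.00956 (adjusted p = 0.261 with an estimated correlation). Interferon-stimulated genes gave 14 rises and 4 falls among 28, or 16 and 4 adjusted over the list alone. Herc6 rose by 1.78 ± 0.14, Rsad2 by 1.65 ± 0.20, Usp18 by 1.40 ± 0.12 and Oasl1 by 1.34 ± 0.13, while Bst2 was among the falls. The list's adjusted p was 0.000503 (adjusted p = 0.261 with an estimated correlation).

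Genes of division, respiration and subset identity moved mostly down. Of 39 cell cycle genes 36 fell and 1 rose, Tk1 (1.13, named after its value was seen), or 38 and 1 adjusted over the list alone. The falls were led by Hmmr (-1.68 ± 0.16), Bub1 (-1.41 ± 0.16) and the DNA replication regulator E2f8 (-1.35 ± 0.18), at an adjusted p of 3.21e-19 (adjusted p = 0.198 with an estimated correlation). Of 31 mitochondrial respiration genes 25 fell and none rose, with the same counts adjusted over the list alone. Uqcrb fell by 1.19 ± 0.15 and Ndufa5 by 1.02 ± 0.18, and the list's adjusted p was 1.53e-12 (adjusted p = 0.272 with an estimated correlation). Glycolysis genes gave 5 falls, including Ldha (-1.37 ± 0.19), Pgam1 and Hk2, and 1 rise among 15, with the same counts adjusted over the list alone. The rise was of Pfkfb3 (2.80 ± 0.13), which makes an activator of glycolysis. The list's adjusted p of 0.0126 became 0.0701 after loess normalization, 0.193 in genes above the median of all values and 0.0813 in those above the 30th percentile, and fry gave 0.0929 (adjusted p = 0.261 with an estimated correlation). Among 23 genes of XCR1+ dendritic cell identity 14 fell and 3 rose, or 15 and 3 adjusted over the list alone. Tlr3, Naaa (-1.92 ± 0.26) and Clnk (-1.88 ± 0.23) fell, and Ly75, the gene of the uptake receptor DEC-205, rose (2.13 ± 0.13), as did Id2 and Batf3, both named after their values were seen. The adjusted p was 0.00039 (adjusted p = 0.359 with an estimated correlation).

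Other function lists were not called by camera in this comparison, while fry called class I presentation (adjusted p = 0.00403), liver X receptor targets (0.00136) and apoptosis regulators (0.00218) up. Among 24 pattern recognition and uptake receptors 8 fell, led by Tlr3 and Fcgr2b (-2.03 ± 0.17), and 4 rose, including Ly75 and Tlr1 (1.93 ± 0.18). These counts were the same adjusted over the list alone, and the list's adjusted p was 0.303. Class I presentation genes gave 7 rises and 1 fall among 15, the same adjusted over the list alone (adjusted p = 0.186, and 0.0344 after loess). Nlrc5, which activates class I genes, rose by 2.53 ± 0.15, with 1.54 to 2.84 over its 19 rows, and Pdia3 fell by 0.67 ± 0.15. In class II presentation 2 of 13 genes rose, Lgmn (1.34 ± 0.12) and Ifi30 (1.21 ± 0.10), and 5 fell, among them H2-DMa (-1.33 ± 0.19) and Ciita, the class II transactivator (1.99-fold lower), again the same adjusted over the list alone (adjusted p = 0.313). Apoptosis regulators gave 6 rises and 3 falls among 17, or 7 and 4 adjusted over the list alone (adjusted p = 0.351). Fas rose by 2.95 ± 0.15, Bcl2l11 by 1.94 ± 0.13, and Casp6 fell by 1.94 ± 0.20. Of 20 cholesterol synthesis and uptake genes 3 rose, Idi1 (1.28 ± 0.19), Hmgcs1 (1.13 ± 0.18) and Mvd, and 2 fell, Ebp and Nsdhl, or 3 and 3 adjusted over the list alone (adjusted p = 0.733). Nsdhl no longer passed without immature replicate 2 (adjusted p = 0.0564) or 3 (0.0611). Targets of the liver X receptor gave 4 rises, including Apol7c (1.45 ± 0.12) and Abcg1 (1.19 ± 0.15), and 2 falls among 12, or 6 and 2 adjusted over the list alone (adjusted p = 0.0931). Without CCR7+Il12b- replicate 3 that list's adjusted p was 0.0455, after loess 0.0293 and after the quantile step 0.0229. Immediate-early and heat-shock genes, taken as signs of handling, gave 2 rises and 5 falls among 21, or 3 and 6 adjusted over the list alone (adjusted p = 0.637), with Dusp2 up (1.38 ± 0.12) and Ier2 (-1.05 ± 0.15) and Fos (-1.03 ± 0.20) down.

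Markers of other cells were measured beside these groups. Of the marker lists that camera did not call, fry called T cell (adjusted p = 0.030), neutrophil (0.0360) and erythroid markers (0.00893) up and plasmacytoid markers (0.00164) down. The list medians were 0.247 for T cell, 0.115 for neutrophil and 0.153 for erythroid markers. Olfactory and vomeronasal receptor genes had a median of 0.0979 here, and fry does not compare a list with other genes. CD11b+ dendritic cell markers gave 8 rises and 1 fall among 16, or 9 and 1 adjusted over the list alone. Tmem176a rose by 2.84 ± 0.17, Tmem176b by 2.25 ± 0.15 and Sirpa by 1.08 ± 0.18, and Cd209a fell. The list's adjusted p was 0.00033 (adjusted p = 0.235 with an estimated correlation), and 13 of its 16 genes were above background in immature XCR1+ cells. Monocyte and macrophage markers gave 3 rises, Spic (3.15 ± 0.22), Vcam1 (2.57 ± 0.17) and Adgre1, and 5 falls, among them Ccr2 and Lyz2 (-1.45 ± 0.26), out of 17 (adjusted p = 0.844). The list's median was 0.05, its mean 0.03, and its test direction down. B cell markers gave 4 rises among 13, including Ms4a1 (1.51 ± 0.17), and a fall of Fcrla (-1.16 ± 0.16), or 5 and 2 adjusted over the list alone (adjusted p = 0.174). Plasmacytoid dendritic cell markers gave 2 rises and 5 falls among 10, or 3 and 5 adjusted over the list alone (adjusted p = 0.19), with Siglech at -1.24 ± 0.11. Of 11 T cell markers only Cd3e rose (0.37 ± 0.12), and none passed adjusted over the list alone (adjusted p = 0.153). Of 12 NK cell markers 2 rose, Nkg7 and Il2rb, the latter below the background mark in both groups, and 2 fell, Klrd1 and Klrk1 (-0.97 ± 0.23), as adjusted over the list alone (adjusted p = 0.47). No neutrophil marker of 13 passed either way (adjusted p = 0.271), and of 8 erythroid markers Car2 (at least 1.68-fold) and Alas2 (0.46 ± 0.10) rose, over all genes and adjusted over the list alone (adjusted p = 0.102). The counts for monocyte markers were the same adjusted over the list alone. Leaving out single samples ended the calls of Klrd1 (adjusted p = 0.0795 without immature replicate 3 and 0.0681 without CCR7+Il12b- replicate 2) and of Cd3e (0.0928 and 0.181 without immature replicates 1 and 3, and 0.118 and 0.121 without CCR7+Il12b- replicates 1 and 2). Those of Nkg7 ended without immature replicate 2 or 3 or CCR7+Il12b- replicate 1 or 3 (adjusted p from 0.0683 to 0.0999), and those of Il2rb without any 1 immature replicate or CCR7+Il12b- replicate 2 (0.0663 to 0.113).

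CCR7+Il12b+ cells were compared with the same immature samples. Cd63 rose at least 111-fold (n = 2 against 3, adjusted p = 2.70e-09), Anxa3 at least 90.8-fold, H2-M2 at least 52.9-fold, Socs2 at least 50.8-fold and Slco5a1 at least 33.1-fold, and the rows of Socs2 gave log2 changes of 4.16 and 6.23 as measured. Zfp872 and Sema6d, the gene of a semaphorin, rose at least 35.8-fold and 31.5-fold. Large falls were those of Naaa, a lysosomal acid amidase (28.2-fold, -4.82 ± 0.29 SE), Tlr3 (-4.82 ± 0.34), Entpd1, the gene of the ectonucleotidase CD39 (at least 13.5-fold), and Serpinb2 (at least 17.0-fold). Arsb, a lysosomal sulfatase, fell 16.6-fold and P2ry14, a receptor for UDP-glucose, 16.2-fold.

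In this comparison 6383 genes changed in limma's moderated test, 2816 higher and 3567 lower, and 2535 of them at least 2-fold as measured, 899 up and 1636 down. Over all genes, 11387 of 19938 showed no overlap between the samples of both groups, where chance gives 20%.

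All 19 NF-kB genes rose again, also adjusted over the list alone, with Birc2 at 3.42 ± 0.12 (2.38 to 3.42 over its rows) and Relb at 3.15 ± 0.14 (adjusted p = 8.41e-15, and adjusted p = 0.264 with an estimated correlation). Co-stimulatory and co-inhibitory genes gave 14 rises and 3 falls among 18, the same adjusted over the list alone. Tnfrsf4 rose 24.1-fold and Pvr 8.92-fold, and Havcr2, the gene of TIM-3, fell 13.2-fold, and Cd86, named after its value was seen, fell by 0.96. The list's adjusted p was 0.000162 (adjusted p = 0.264 with an estimated correlation). Cytokine genes gave 12 rises and 5 falls among 22, as adjusted over the list alone, with Il21r up 22.2-fold, Il15ra 21.8-fold and Il7r 14.8-fold, and Ifngr1 at -3.20. The adjusted p was 0.0153 (adjusted p = 0.433 with an estimated correlation), and without CCR7+Il12b+ replicate 1 it was 0.068. Tolerance-associated genes gave 10 rises and 4 falls among 19, or 11 and 4 adjusted over the list alone. Arg2, the gene of arginase 2, rose at least 5.93-fold and Ctla4 fell (-2.36 ± 0.44), at an adjusted p of 0.00578 (adjusted p = 0.325 with an estimated correlation). Of 20 cholesterol synthesis and uptake genes 9 rose and 2 fell, or 13 and 2 adjusted over the list alone. Idi1 rose by 2.82 ± 0.21, Hmgcs1 by 2.33 ± 0.20, Fdft1 by 1.35 ± 0.17 and Mvd by 1.27 ± 0.17, all enzymes of sterol synthesis, while Ebp was among the falls. The list's adjusted p was 0.00191 (adjusted p = 0.463 with an estimated correlation).

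Cell cycle genes gave 36 falls and 1 rise among 39, or 37 and 1 adjusted over the list alone, with Ccna2 down 8.37-fold and Bub1 at least 5.12-fold and Tk1 up by 1.16. Their adjusted p was 6.47e-23 (adjusted p = 0.264 with an estimated correlation). Identity genes gave 18 falls and 3 rises among 23, or 18 and 5 adjusted over the list alone. Naaa, Tlr3, Rab7b (-3.92 ± 0.25) and Gcsam (-3.75 ± 0.41) fell, and Ly75 (2.64 ± 0.15), Id2 and Batf3 rose (adjusted p = 1.24e-07, and adjusted p = 0.342 with an estimated correlation). Of 31 respiration genes 26 fell and none rose, or 29 and none adjusted over the list alone, with Uqcrb at -1.61 ± 0.17 and Ndufs3 at -1.59 ± 0.19 (adjusted p = 3.82e-13, and adjusted p = 0.342 with an estimated correlation). Glycolysis genes gave 9 falls among 15 and the rise of Pfkfb3 (3.23 ± 0.15), or 10 and 2 adjusted over the list alone. Ldha fell by 2.85 ± 0.21 and Hk2, a hexokinase gene, changed by -1.53 ± 0.17, at an adjusted p of 0.00448 (adjusted p = 0.312 with an estimated correlation). In genes above the median of all values the glycolysis list's adjusted p was 0.115. Class II presentation gave 8 falls and 2 rises among 13, the same adjusted over the list alone. H2-DMa, which loads peptides, fell by 2.78 ± 0.21, Ciita by 2.57 ± 0.17 and H2-Ob by 1.92 ± 0.27, and Lgmn rose by 1.90 ± 0.13. That list's adjusted p was 0.0104 (adjusted p = 0.433 with an estimated correlation), and 0.142 in genes above the median of all values and 0.0695 in those above the 30th percentile. Pattern recognition genes gave 10 falls and 3 rises among 24, the same adjusted over the list alone, with Fcgr2b at -2.61 ± 0.19 and Cd207 at -2.16 ± 0.28. Their adjusted p of 0.0463 (adjusted p = 0.312 with an estimated correlation) became 0.0868 without CCR7+Il12b+ replicate 1, where the list's median was 0.03 in place of -0.11. It was 0.0533 without CCR7+Il12b+ replicate 2 and 0.0502 without CCR7+Il12b- replicate 1. The call also ended after median centring (0.0528), loess (0.0648) and the quantile step (0.0527), in genes above the median of all values (0.207, list median -0.82) and in those above the 30th percentile (0.0932, list median -0.67).

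The remaining function lists were not called by camera. The fry test called migration and chemokine genes (adjusted p = 0.000127 each), class I presentation (0.00198), liver X receptor targets (0.00349) and apoptosis regulators (0.00395) up. Migration genes gave 9 rises and 5 falls among 17, or 9 and 6 adjusted over the list alone (adjusted p = 0.169), with Fscn1 up 40.0-fold and Itgae down 11.6-fold. Chemokines gave 8 rises and 5 falls among 16, or 8 and 6 adjusted over the list alone (adjusted p = 0.31). Ccl5 rose 21.4-fold, Ccl22 18.7-fold and Ccl19 9.80-fold, and Ccl4, Cxcl9 and Cxcl10 were among the falls, with -1.69, -1.29 and -1.26. Interferon-stimulated genes gave 10 rises and 6 falls among 28, or 10 and 7 adjusted over the list alone (adjusted p = 0.495), with Herc6 at 2.56 ± 0.16 and Irf7, a transcription factor of the interferon response, at -1.74 ± 0.17. In class I presentation 7 of 15 genes rose and 3 fell, also adjusted over the list alone (adjusted p = 0.179, and 0.0166 after loess), with Nlrc5 at 3.02 ± 0.17 (2.05 to 3.30 over its rows) and Pdia3 at -1.20 ± 0.16. Apoptosis regulators gave 6 rises and 6 falls among 17, or 7 and 6 adjusted over the list alone (adjusted p = 0.903), and their median of -0.09 had the opposite sign to their mean of 0.33 and to the test. Fas rose 19.0-fold and Bcl2l1 by 2.29 ± 0.18, and Casp6 fell at least 6.80-fold. Liver X receptor targets gave 3 rises, Abcg1 (1.79 ± 0.17), Apol7c and Mylip, and falls of Scd2 and Lpcat3 among 12, the same adjusted over the list alone (adjusted p = 0.477). Immediate-early genes gave 6 rises and 9 falls among 21, or 7 and 9 adjusted over the list alone (adjusted p = 0.405). Their median was 0.06 with a mean of -0.26 and a test direction of down, and Egr2 (-1.93 ± 0.17) and Ier2 (-1.81 ± 0.17) fell most.

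Among markers of other cells, plasmacytoid markers gave 5 falls and no rise among 10, as adjusted over the list alone, with Ccr9 down at least 4.17-fold and Siglech at -1.42 ± 0.12. Their adjusted p was 0.0204 (adjusted p = 0.264 with an estimated correlation), and 0.0636 without CCR7+Il12b+ replicate 1, 0.136 in genes above the median of all values and 0.0932 in those above the 30th percentile. CD11b+ dendritic cell markers gave 4 rises, Tmem176a (3.20 ± 0.19), Tmem176b, Esam and Irf4 (named after its value was seen), and 2 falls, Cd209a (-2.03 ± 0.17) and Cd4, among 16, also adjusted over the list alone (adjusted p = 0.691). Monocyte and macrophage markers gave 3 rises and 6 falls among 17, as adjusted over the list alone (adjusted p = 0.75), with Vcam1 at 3.17 ± 0.19, Spic at 3.06 ± 0.24 and Lyz2 at -3.11 ± 0.29. Their median was 0.16 and their mean -0.17. B cell markers gave 1 rise, of Ms4a1 (0.91 ± 0.19), and 4 falls, of Fcrla, Bank1, Cd22 and Cd79b, among 13, as adjusted over the list alone (adjusted p = 0.478), with a median of 0.04 and a mean of -0.18. Of 11 T cell markers Ubash3a rose and Cd5 and Cd3d fell, or 3 rises and 2 falls adjusted over the list alone (adjusted p = 0.75). Ubash3a did not pass without immature replicate 3 (adjusted p = 0.0577) or CCR7+Il12b+ replicate 2 (0.162), Cd5 without CCR7+Il12b+ replicate 1 (0.0575), and Cd3d, below the background mark in both groups, without immature replicate 2 or 3 or CCR7+Il12b+ replicate 1 (0.0863 to 0.147). Klrd1 (at least 8.54-fold) and Klrk1 (-2.55 ± 0.26) fell among 12 NK markers, over all genes and adjusted over the list alone (adjusted p = 0.75), where the median was 0.12 and the mean -0.37. Of 13 neutrophil markers Mmp9, below the background mark in both groups, passed, though not without immature replicate 1 or 3 or either CCR7+Il12b+ replicate (adjusted p from 0.0856 to 0.139), and none adjusted over the list alone (adjusted p = 0.353), and Car2 and Alas2 rose among 8 erythroid markers, as adjusted over the list alone (adjusted p = 0.303). With fry, CD11b+ dendritic cell (adjusted p = 0.0471), neutrophil (0.0215) and erythroid markers (0.0153) were called up.

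Across the 19938 genes the changes of both matured fractions against immature cells were alike in sign and differed in size. Their Pearson correlation across genes, which are not independent replicates, was 0.927, where unchanged groups sharing the same immature samples gave 0.447 in 100 simulations. The covariance was 0.359 against 0.00959 simulated, a difference of 0.349, and 85.5% of genes had the same sign against 64.7% simulated. Cd63, Anxa3 and Socs2 were among 1533 genes higher in both fractions, where independent lists would share 256, and Tlr3, Serpinb2 and Naaa among 2644 lower in both, where independent lists would share 517. The 3 immature samples cannot be split with 2 in each part, so part of the excess may come from the shared controls. The slope of CCR7+Il12b- on CCR7+Il12b+ changes was 0.636, and of 4177 genes called in both with the same sign, 3768 (90.2%) had the larger change in CCR7+Il12b+ cells. Only 5 genes, chosen here after their values were seen, were called with opposite signs: Cd79b, Gpr183, Siglecg and Syk were higher in CCR7+Il12b- and lower in CCR7+Il12b+ cells than in immature cells, and Nans the reverse. Several of these calls lay near the threshold of limma's moderated test. The adjusted p was 0.0406 for the rise and 0.0499 for the fall of Cd79b. It was 0.0471 for the fall of Nans and 0.0391 for the rise of Siglecg, and at most 0.0205 for the other calls. For Cd79b the rise in CCR7+Il12b- cells did not pass without immature replicate 1 (adjusted p = 0.129). Leaving out immature replicate 2 or any 1 CCR7+Il12b- replicate also ended that call, with adjusted p from 0.0511 to 0.134.

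**Figure D3:**
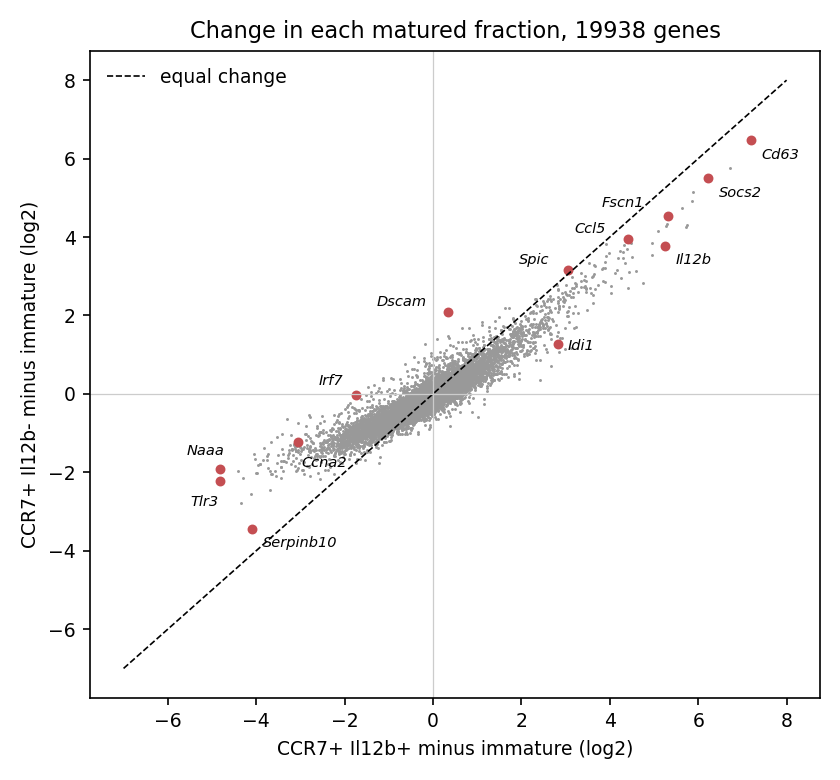
Log2 change against immature cells of each gene in the CCR7+Il12b+ fraction (x axis) and in the CCR7+Il12b- fraction (y axis), as measured, with named genes labelled. The points follow a slope of 0.636 with a correlation of 0.927, where shared immature samples alone gave 0.447.

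The direct comparison of both matured fractions asked what accompanies the reporter among CCR7+ cells. Psca, a surface antigen, was at least 2.70-fold higher in CCR7+Il12b+ cells (n = 2 against 3, adjusted p = 9.37e-05). Csf1, the gene of a macrophage growth factor, rose by 1.96 ± 0.14 (SE), the transcription factor gene Ehf by 1.92 ± 0.19, Arg2 by 1.85 ± 0.18, Clu, the gene of clusterin, by 1.78 ± 0.21, and Eno2, an enolase gene, by 1.70 ± 0.19. Large falls were those of Naaa (7.47-fold, -2.90 ± 0.29), Ifi205 (-2.67 ± 0.21), Tlr3 (-2.59 ± 0.34), Arsb (-2.53 ± 0.32) and Entpd1 (at least 3.47-fold). Cd53, a tetraspanin, Slc9a9 and Slamf8 changed by -2.43 to -2.44, and Klrd1, the gene of CD94, fell at least 4.19-fold.

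Between these fractions 1412 genes differed in limma's moderated test, 521 higher and 891 lower in CCR7+Il12b+ cells, with 397 at least 2-fold as measured, 93 up and 304 down. The samples of both groups did not overlap for 5904 of all 19938 genes, where chance gives 20%. Of the 1412, 666 (47.2%) had also fallen in CCR7+Il12b- against immature cells and fell further, and 339 (24.0%) had risen and rose further. The count was 712 without CCR7+Il12b+ replicate 1, without CCR7+Il12b- replicate 1 it was 925 and without CCR7+Il12b- replicate 2 it was 786, while without CCR7+Il12b- replicate 3 it was 1771. The balance depended on single CCR7+Il12b+ samples, with 191 higher and 521 lower without replicate 1, and 494 higher and 517 lower (1011 in all) without replicate 2.

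Of 20 cholesterol synthesis and uptake genes 9 were higher in CCR7+Il12b+ cells and none lower, or 13 and none adjusted over the list alone. Idi1 rose by 1.54 ± 0.21, Hmgcs1 by 1.21 ± 0.20, Msmo1 by 1.09 ± 0.18 and Fdft1 by 1.02 ± 0.17, at a list adjusted p of 1.66e-10 (adjusted p = 0.209 with an estimated correlation). The adjusted p of Hmgcs1 was 0.0539 and that of Msmo1 0.0591 without CCR7+Il12b+ replicate 1. Liver X receptor targets gave no rise and 2 falls among 12, or 1 and 2 adjusted over the list alone (adjusted p = 0.623). NF-kB genes gave 2 rises, including Birc2 (0.69 ± 0.12), and no fall among 19, or 4 and none adjusted over the list alone. The list's adjusted p was 8.02e-05 (adjusted p = 0.35 with an estimated correlation), and 0.0644 with fry. Without CCR7+Il12b+ replicate 1 it was 0.0622, with Birc2 at 0.0642.

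Subset identity genes gave 15 falls and no rise among 23, or 16 falls and 3 rises adjusted over the list alone. Naaa, Tlr3, Rab7b (-2.13 ± 0.25), Xcr1 and Clec9a, an uptake receptor for dead cells (-1.61 ± 0.18), fell (adjusted p = 1.17e-11, and adjusted p = 0.209 with an estimated correlation). Cell cycle genes gave 27 falls and no rise among 39, or 30 falls adjusted over the list alone, with Ccna2 at -1.83 ± 0.24 and Kif11 at -1.56 ± 0.18 (adjusted p = 2.43e-23, and adjusted p = 0.186 with an estimated correlation). Class II presentation gave 5 falls and the rise of Lgmn (0.56) among 13, or 7 and 1 adjusted over the list alone. Ciita fell by 1.57 ± 0.17, H2-DMa by 1.46 ± 0.21 and H2-Oa by 1.33 ± 0.16 (adjusted p = 4.34e-05, and adjusted p = 0.209 with an estimated correlation). In class I presentation 1 of 15 genes rose and none fell, or 2 and 1 adjusted over the list alone (adjusted p = 0.127). That list's adjusted p was 0.0264 without CCR7+Il12b+ replicate 2 and 0.0147 after loess. Pattern recognition genes gave 6 falls and no rise among 24, or 7 and 1 adjusted over the list alone, with Cd36 at -1.29 ± 0.17 (adjusted p = 0.00292, and adjusted p = 0.186 with an estimated correlation). Respiration genes gave 5 falls among 31 and no rise, or 11 falls adjusted over the list alone, with a median of -0.39 (adjusted p = 1.33e-06, adjusted p = 0.428 with an estimated correlation, and 0.209 with fry). Of 15 glycolysis genes 2 fell, including Ldha (-1.47 ± 0.21), or 4 falls and 1 rise adjusted over the list alone (adjusted p = 0.00702, and adjusted p = 0.246 with an estimated correlation). In genes above the median of all values the adjusted p of glycolysis was 0.0541, and with fry it was 0.0644.

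Interferon-stimulated genes gave 6 falls and 1 rise among 28, or 11 and 2 adjusted over the list alone. Irf7 fell by 1.71 ± 0.17, at a list adjusted p of 0.000514 (adjusted p = 0.257 with an estimated correlation), which was 0.0664 without CCR7+Il12b+ replicate 2. Chemokines gave 4 falls, including Cxcl9 (-1.33 ± 0.12) and Cxcl10 (-0.93 ± 0.15), both ligands of CXCR3, and 3 rises among 16, or 6 and 5 adjusted over the list alone (adjusted p = 0.118). With fry it was 0.0446. Without CCR7+Il12b- replicate 3 the camera adjusted p was 0.0483 and without CCR7+Il12b+ replicate 1 it was 0.0441. Cytokine genes gave 6 rises and 4 falls among 22, or 7 and 4 adjusted over the list alone (adjusted p = 0.445), with Il15ra at 1.35 ± 0.15, Il15 at 1.27 ± 0.20 and Ifngr1, a receptor chain for interferon gamma, at -1.80 ± 0.21. The cytokine list's adjusted p was 0.0438 without CCR7+Il12b+ replicate 2. Co-stimulatory and co-inhibitory genes gave 4 rises, Tnfrsf4 (1.46 ± 0.20), Pvr, Cd70 and Cd200, and 2 falls, including Havcr2 (-2.18 ± 0.22), among 18, or 5 and 3 adjusted over the list alone (adjusted p = 0.344). Leaving out CCR7+Il12b+ replicate 1 gave adjusted p of 0.0594 for Pvr and 0.0668 for Cd70, and leaving out CCR7+Il12b+ replicate 2 gave 0.0363 for the list. Migration genes gave 3 rises, S1pr1 (adjusted p = 0.00187), Anxa3 and Fscn1, and 5 falls, among them Ccr9 (at least 1.33-fold), out of 17, or 5 and 5 adjusted over the list alone (adjusted p = 0.571). Tolerance-associated genes gave 3 rises, including Arg2, and 2 falls among 19, or 4 and 2 adjusted over the list alone (adjusted p = 0.625). Apoptosis regulators gave 2 rises, including Fas (1.29 ± 0.17), and 3 falls among 17, also adjusted over the list alone (adjusted p = 0.648), with a median of 0.03 and a mean of -0.03. Immediate-early genes gave 3 falls, including Egr2 (-1.46 ± 0.17), among 21, or 6 adjusted over the list alone (adjusted p = 0.167), with a median of 0.06 and a mean of -0.20. Without CCR7+Il12b+ replicate 1 that list's adjusted p was 0.00328, where its median was -0.17, and without CCR7+Il12b- replicate 3 it was 0.0359, after the quantile step 0.0269 and with a replicate block 0.0459.

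Markers of other cells were lower or did not pass in CCR7+Il12b+ against CCR7+Il12b- cells. CD11b+ dendritic cell markers gave 5 falls among 16, S100a4 (-1.38 ± 0.24), Cd4, Cd209a, Sirpa and Clec4a4 (named after its value was seen, and below the background mark in both groups), or 8 adjusted over the list alone (adjusted p = 0.000514, and adjusted p = 0.209 with an estimated correlation). Without CCR7+Il12b+ replicate 1 the adjusted p was 0.0510 for S100a4, 0.0783 for Cd4, 0.0532 for Cd209a and 0.163 for Sirpa, which also missed the threshold without CCR7+Il12b- replicate 1 (0.05003). B cell markers gave 2 falls, Cd79b (-1.15 ± 0.20) and Cd22 (-0.63 ± 0.12), among 13, or 8 adjusted over the list alone (adjusted p = 0.000121, and adjusted p = 0.246 with an estimated correlation), and without CCR7+Il12b+ replicate 1 their adjusted p were 0.0732 and 0.0868. Plasmacytoid markers gave 2 falls, Ccr9 and Atp1b1 (at least 2.13-fold), among 10, or 3 adjusted over the list alone (adjusted p = 0.00304, and adjusted p = 0.186 with an estimated correlation). Klrd1 and Klrk1 (-1.58 ± 0.26) fell among 12 NK markers, also adjusted over the list alone, with a median of -0.08 (adjusted p = 0.0422, and adjusted p = 0.209 with an estimated correlation). Leaving out either CCR7+Il12b+ replicate, CCR7+Il12b- replicate 1 or immature replicate 1 raised the NK list's adjusted p to 0.0515 to 0.0732, and a fit on the compared groups alone gave 0.0522. Monocyte and macrophage markers gave 3 falls, Lyz2 (-1.65 ± 0.29), Cd68 (-1.29 ± 0.23) and a further gene, among 17, or 3 and 1 rise adjusted over the list alone (adjusted p = 0.35). Without CCR7+Il12b+ replicate 1 the adjusted p of Lyz2 was 0.0696, and without replicate 2 that of Cd68 was 0.0599. No T cell marker of 11 (adjusted p = 0.191), neutrophil marker of 13 (adjusted p = 0.661) or erythroid marker of 8 (adjusted p = 0.789) passed, over all genes or adjusted over the list alone. Car2 was at -0.18 ± 0.14, and the erythroid median of 0.02 had the opposite sign to the mean of -0.02. The T cell list's adjusted p was 0.0457 without CCR7+Il12b+ replicate 2.

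**Figure D4:**
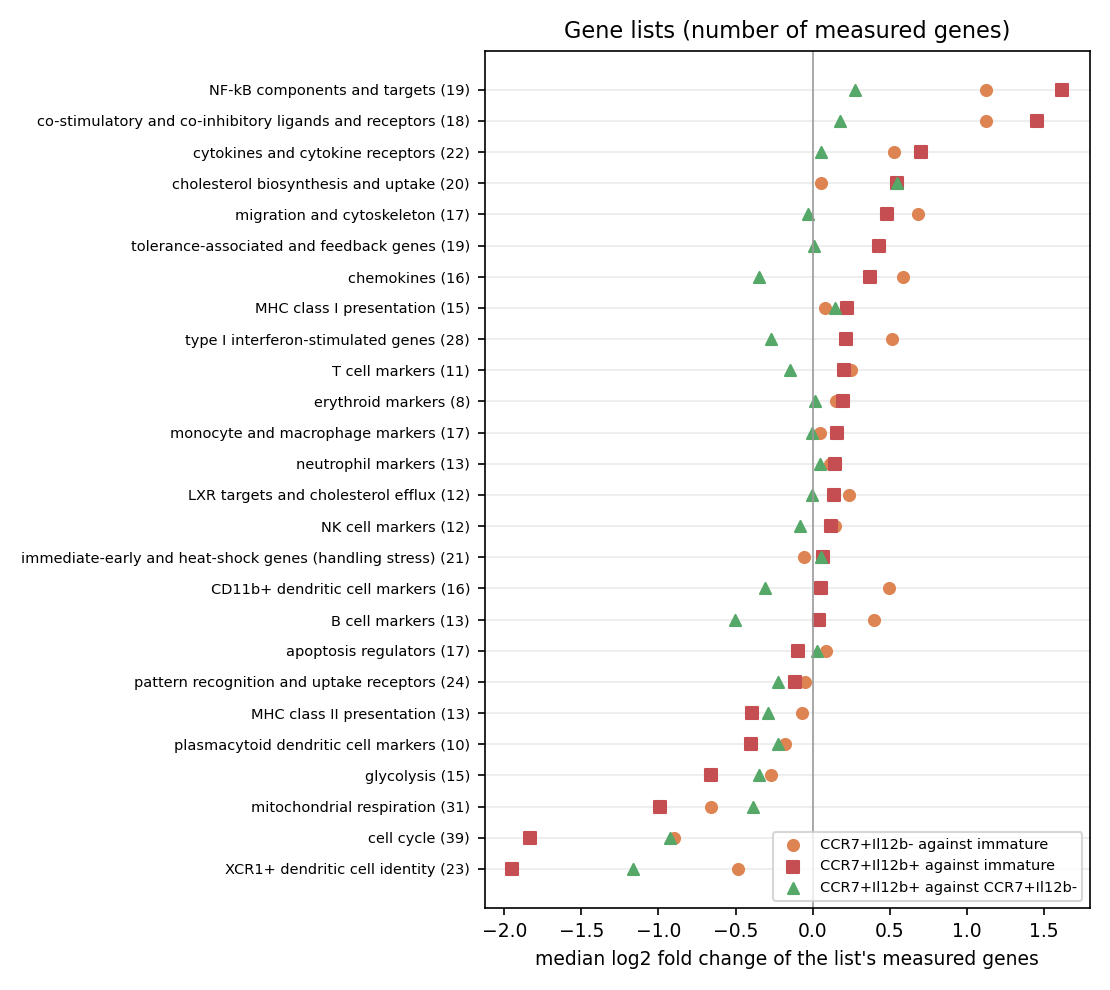
Median log2 change of the genes of each fixed list in the 3 pairwise comparisons, 1 row per list. NF-kB genes have medians of 1.12 and 1.62 against immature cells and 0.28 between the matured fractions, and cell cycle genes -0.90, -1.83 and -0.93.

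Both matured fractions together were also set against immature cells, as the mean of the matured group means. Of the genes tested, 6616 changed in limma's moderated test, 2866 higher and 3750 lower, and 1878 of them at least 2-fold as measured. Over all genes, 6895 of 19938 showed no overlap between samples, where chance gives 3.57%. NF-kB genes (19 of 19), co-stimulatory genes (14 of 18), cytokine genes (12 of 22) and tolerance-associated genes (10 of 19) rose in the 4 lists called up, with adjusted p of 1.01e-15, 3.36e-05, 0.00952 and 0.00235. The same numbers of members rose adjusted over the list alone, apart from 12 for the tolerance list. Cell cycle (38 of 39), respiration (27 of 31), identity (17 of 23) and glycolysis genes (9 of 15) fell in the 4 lists called down, with adjusted p of 7.56e-22, 1.51e-13, 1.86e-06 and 0.0053. Adjusted over the list alone 38, 29, 17 and 10 of them fell. These lists were called by camera, where fry called 22 of 26. None of the 8 calls held with an estimated correlation, where the smallest value was adjusted p = 0.239 with an estimated correlation.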

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

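Some alternatives were added after the data were seen: for single genes array weights, both filters on dim genes, another quantile normalization and the random block, for lists the 30th percentile filter, the mean of rows, the quantile step and fits on the compared groups alone, and for the correlation and covariance the variance models and the block. Single genes were followed across settings only where the naming rule gave them, and the signs of all other genes were not compared. No such named gene called in either setting changed its sign, and no list called in either changed its test's direction. Among list medians 67 of 1482 changed sign, 2 of them with a call in either setting, both without CCR7+Il12b+ replicate 1. These were pattern recognition genes in CCR7+Il12b+ against immature cells (-0.11 to 0.03) and immediate-early genes between the matured fractions (0.06 to -0.17). Some settings among the 1482 keep the fold changes of the main fit, so no sign could change there. These are the estimated correlation, fry, the robust variance with trend and fits on the compared groups alone. Leaving out a sample outside a comparison also keeps its fold changes. Of 6082 values of named genes under an alternative, 5810 stayed on their side of the threshold, 265 lost and 7 gained a call. Of 1560 list values 1423 stayed, 67 lost and 70 gained one. Most gains came with another test rather than other processing. Fry gave 16 of them, and a form of fry that counts changes in either direction gave 38. Neither compares a list with other genes, as camera does. An estimated correlation ended all 37 list calls of the 3 pairwise comparisons. With every row of the table, 771 rows differed between the matured fractions, and the correlation and covariance of the changes against immature cells were 0.882 and 0.316. In genes above the median of all values the covariance was 0.617 and in those above the 30th percentile 0.498, with fewer genes tested. Against a null bound of 2-fold, 256 genes differed in CCR7+Il12b- against immature cells, 220 higher and 36 lower, where the counts without that bound had more lower than higher. It was 1051 in CCR7+Il12b+ against immature cells (451 higher, 600 lower), 8 between the matured fractions (2 and 6) and 717 in both against immature (379 and 338). At an adjusted p under 0.01 the counts were 2934 for CCR7+Il12b- against immature cells and 584 between the matured fractions, by construction of a stricter threshold. Leaving out 1 sample gave 3290 to 4962 genes for CCR7+Il12b- against immature, 4982 to 6617 for CCR7+Il12b+ against immature, 5034 to 7197 for both against immature, and 712 (without CCR7+Il12b+ replicate 1) to 1771 (without CCR7+Il12b- replicate 3) between the matured fractions. The correlation then ranged from 0.902 to 0.931 and the covariance from 0.327 to 0.384, and a lone CCR7+Il12b+ sample was assumed to vary like the other groups. Apart from fewer samples, the cause of these differences was not tested. Same-numbered samples did not deviate together in all 7 pairs (r from -0.169 to 0.216). Pairs with an immature sample gave -0.169 to 0.0581, and those of the matured fractions 0.216 and 0.0932. Deviations within each small group sum to 0, so this check has little power and does not exclude a pairing. Of 8 samples, 3 correlated best with their own number, and with a replicate block the counts were 4318, 5767, 1153 and 6165. Fits on the compared groups alone are the same fit for both fractions against immature cells and were not repeated there. Values below the background mark limit what can be seen of weakly expressed genes.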

Other observations

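The tests of a mixture of cells and of dividing cells, and the choice of the ribosome genes and of the genes highest in CCR7+Il12b- cells, came after the results were seen. Genes of ribosome production formed a group not among the fixed lists. Of 58 ribosome biogenesis genes measured, 48 fell and none rose in CCR7+Il12b- against immature cells (55 falls adjusted over the list alone), with a median log2 change of -0.76. In CCR7+Il12b+ cells 56 fell (57 adjusted over the list alone), with a median of -1.21, and between the matured fractions 23 fell (34 adjusted over the list alone), with a median of -0.51. Rrs1, needed for ribosome assembly, changed by -1.44 ± 0.13 (SE, n = 3) and fell at least 4.06-fold (n = 2) against immature cells, Nop58, a core nucleolar protein gene, changed by -1.47 ± 0.21 and -3.05 ± 0.24, Dkc1, whose product modifies ribosomal RNA, by -1.85 ± 0.15 and by a fall of at least 4.86-fold, and Polr1a, the largest subunit of RNA polymerase I, by -1.38 ± 0.14 and -2.50 ± 0.16. The list's camera p was 0.0293, 0.0230 and 0.0352 with an estimated correlation in the 3 comparisons, unadjusted and on a list picked from these data. Of 76 mitochondrial ribosome genes 58 fell and 1 rose in CCR7+Il12b- cells (68 and 2 adjusted over the list alone) and 61 fell and 2 rose in CCR7+Il12b+ cells (64 and 2), with medians of -0.76 and -0.95, led by Mrps28 (-1.43 ± 0.19 and -2.72 ± 0.21). Between the matured fractions 8 of them fell (12 adjusted over the list alone), with a median of -0.17. The estimated-correlation p of these genes was 0.0840, 0.101 and 0.373.

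A small set of genes was highest in the CCR7+Il12b- fraction. Of the 1412 genes that differed between the matured fractions, 56 (3.97%) were higher in CCR7+Il12b- cells than in both other groups and 12 (0.850%) lower than in both. The same CCR7+Il12b- samples enter both steps with opposite sign, so error in them favours such patterns. Dscam, a cell adhesion molecule, was at 4.81, 6.89 and 5.14 (log2 means) in immature, CCR7+Il12b- and CCR7+Il12b+ cells, with a rise of at least 3.75-fold and then a change of -1.75 ± 0.23. St8sia1, a ganglioside sialyltransferase gene, changed by 1.26 ± 0.22 and -1.43 ± 0.24, and S100a4 by 0.94 ± 0.21 and -1.38 ± 0.24. Gpr183, whose product guides cells by oxysterols, changed by 0.77 ± 0.16 and -1.40, and Sirpa, a marker of CD11b+ dendritic cells, by 1.08 ± 0.18 and -0.91 ± 0.20. Without CCR7+Il12b+ replicate 1 the adjusted p of the second step was 0.0510 for S100a4 and 0.163 for Sirpa. Among the 12 genes lowest in CCR7+Il12b- cells were Nans, Acsl4 and Pml.

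Values of the CCR7+Il12b- fraction lay mostly between those of the other fractions. A mixture of immature cells with cells like the CCR7+Il12b+ fraction would give 1 mixing share for all genes. On the linear scale the median share was 0.542 (SD 0.0736, n = 3) from 278 rising genes and 0.734 (SD 0.0915) from 332 falling genes. The difference of -0.193 (SE 0.0104) goes against that mixture if all arrays share 1 scale, with an error that was not fully measured. That SE covers only the spread over the 3 CCR7+Il12b- samples. All 3 were set against the same means of the other fractions, whose error it leaves out. Shares of single genes overlapped, with 10th to 90th percentiles of 0.320 to 0.801 for rising and 0.580 to 0.829 for falling genes. The difference was -0.347 when array values were taken as compressed with an exponent of 0.7. An offset of the CCR7+Il12b- arrays that would bring both shares together is -0.31 (log2), where genes alike in the other fractions had a median offset of -0.00475. Normalization brings such an offset near 0 in advance, so this value cannot decide whether an offset underlies the difference of the shares. A compressed signal range of the CCR7+Il12b- arrays cannot be told apart from a true intermediate level by the slope of 0.986 over 3264 genes alike in immature and CCR7+Il12b+ cells. Normalization had given the arrays a similar range (SD over genes 0.959 to 0.999 of that of the others), which fixes that slope near 1. A candidate explanation left open is a state of the cells between the others, or a mixture that holds further kinds of cell, neither of which was tested.

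Il12b transcript was raised 13.7-fold in cells sorted as negative for the reporter. CCR7+Il12b+ cells left in that sort would have to make up a share of 0.342 to account for it, and would then set a floor on the ratio of CCR7+Il12b- to CCR7+Il12b+ values of other rising genes. Of 277 such genes 8, or 2.89% (exact 95% interval 1.25 to 5.61%), lay below that floor, including Csf1 and Ehf, with the ratio of Psca taken at its bound, and the median ratio was 0.616. The 1st percentile of the ratio, 0.274, was below 0.342 by more than the 0.05 set for leftover cells, which goes against them as the whole source but rests on the lowest few of the 277 genes. The interval of the share takes the genes as independent, although they were measured on the same arrays, and may be too narrow. It reaches both sides of the 5% set for excluding leftover cells. These cells therefore cannot be told apart from Il12b transcription in reporter-negative cells. Transcript that comes before detectable reporter may also be a source and was not tested.

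Fewer dividing cells could account for the falls of the ribosome genes if these kept a fixed ratio to the fall of cell cycle genes. For ribosome biogenesis the ratio of medians was 0.847 from immature to CCR7+Il12b- cells and 0.553 from there to CCR7+Il12b+ cells, a difference of 0.294 (jackknife SE 0.261, range 0.121 to 0.427 with 1 sample left out). For mitochondrial ribosome genes the ratios were 0.846 and 0.184, a difference of 0.662 (SE 0.370, range 0.444 to 0.933). Both differences lie within 2 of these SE of 0. The jackknife took the 8 arrays as 1 sample, although they form groups of 3, 3 and 2, which makes the SE too large. For mitochondrial ribosome genes, whose difference is close to 2 SE, it therefore decides nothing. A share of dividing cells and a lower level per cell were not told apart with 8 arrays.

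Other splits of the samples were tried. In a 2-group model 5497 genes differed between the 5 CCR7+ and the 3 immature samples, and 1 of 56 splits, the real one, gave as many. The highest other split gave 1938, with CCR7+Il12b- replicate 3 and both CCR7+Il12b+ samples against the rest. A share of 1 in 56 is under 0.05 and is the smallest that these splits can give. It takes the samples as independent, which the labels do not state, so chance is unlikely on that assumption but not excluded. For CCR7+Il12b- against immature samples the real split gave 4962 genes and the highest other 0, with 1 of 10 splits as large, which is too few splits for a share under 0.05.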
